A study of Mus musculus with 126 samples.

How the data were processed

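Single cells were taken from mouse endolymphatic sacs, the part of the inner ear that regulates the endolymph, at E14.5, the embryonic age in days. Complementary DNA was made by Smart-seq2, a plate-based protocol that copies full-length transcripts of 1 cell per well without molecular identifiers, per the labels. The labels assign 33 cells to wild-type animals and 93 cells to animals heterozygous for the Sox9 Y440X allele. They name no animal, litter or plate. Cell titles begin with P9 or P10, prefixes that the labels do not define. All 93 mutant cells and 1 wild-type cell carry P9, and the other 32 wild-type cells carry P10.

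The authors deposited 1 table of FPKM values, fragments per kilobase of transcript scaled to the mapped fragments of the cell, with a row per gene and a column per cell. The submitters' processing notes name HISAT2, SAMtools 0.1.18, Cufflinks, HTSeq and the mouse build mm10, without a role or an order. The strand setting, the annotation release and any filter on reads are not given in the sources used here. The table holds 48555 rows for 48490 gene identifiers. The 49 identifiers with several rows were summed. All 37 rows of the mitochondrial chromosome are listed at 0 in every cell, so mitochondrial content could not be used to judge cell quality. Of the identifiers, 48131 were found in the GENCODE vM21 annotation of the same build, and 88.35% of these had the same coordinates there. Coordinates below are those of the table, counted from 1. A symbol from the lists that was not in the table was looked up by its identifier, which matched Cnmd to the table's Lect1. The other 5 list symbols without a match (Cox4i1, Foxc2, Gins2, Rpl13 and Tubb3) were not analysed here.

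FPKM carries no read number, so the sequencing depth per cell is unknown, and genes listed above 0 stood in for it. The median was 5329 listed genes in wild-type cells (2189 to 6493) and 4423 in mutant cells (2035 to 9358). The FPKM of a cell summed to a median of 462792, with a range of 60901.7 to 16361088.8. In 5 cells the 148-base feature AC155839.1 exceeded 100000 FPKM, which shows how a short feature can take over such a sum. Because a value of 0 can also be a transcript that was not captured, a gene below 1 FPKM is called not detected, never absent.

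Cells with at least 2000 listed genes were kept, which removed 0 cells. No doublet caller was run, since it needs counts. Cells above 6000 listed genes were left out in an alternative instead. Clustering used log2(FPKM + 1) of genes at 1 FPKM or more in at least 3 cells, the 2000 most variable genes, 20 principal components, 15 neighbours and the Leiden algorithm at resolution 1 (scanpy 1.11.5, leidenalg 0.10.2, Python 3.11.15). A cluster was named from 13 marker lists fixed before the data were examined. It took the name of the list with the largest share of members at 1 FPKM in most of its cells, given at least 3 such members.

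Each genotype counts as 1 sample of many cells, because no animal is named. No test between genotypes was therefore made, and no p-value or standard error is given. Shares of cells have exact binomial (Clopper-Pearson) 95% intervals, which cover counting error only and not the spread between animals. For a count of 0, the limit printed as the share allowed is instead 3 counts of the total. In groups of 30 cells or more it is close to a one-sided 95% limit and lower than the upper end of the exact interval. For 0 of 7 cells it is 42.9%, above the exact upper end of 40.96%. Levels are means of log2(FPKM + 1) with the SD over cells (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). In epithelial-like cells, genes at 1 FPKM or more in at least 50% of cells of either genotype were compared, 3375 genes in all. Their median difference, mutant minus wild type, was -0.55 on the log2 scale, so differences are reported relative to this median and called relative differences. A gene listed at 0 in all cells would thus have a relative difference of 0.55, and scarce genes lie above 0 for that reason. The pseudocount of 1 understates differences of scarce genes.

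The genes named were chosen by a rule fixed before the data were examined. They were the 12 lowest and 12 highest compared genes by relative difference that kept their sign and at least 50% of this difference among cells with 3000 to 5000 listed genes and after rescaling each cell to 1000000. Predicted genes, pseudogenes, haemoglobin, mitochondrial and Y-linked genes and Xist were left out of this ranking. A further fixed set of 19 genes of inner ear biology was computed whatever its values, as were the members with the highest and lowest relative difference of each list described. Some of these single-gene values are not used here. For 31 gene lists fixed beforehand, members at 1 FPKM in at least 10% of the epithelial-like cells were used. The median relative difference of a list was placed among those of 10000 random lists of the same size, matched on mean level in 20 bins. The resulting percentile describes these cells and is not a test between genotypes.

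The difference and the list percentile were tested on simulated data, in which wild-type epithelial-like cells were resampled as 2 groups and 200 genes were changed. Among 3273 genes, a 4-fold rise with an expected log2 difference of 1.41 was estimated at a median of 1.51, and a 2-fold rise of 0.68 at 0.75. Reductions to 0.25 and 0.5 of the level, expected at -1.39 and -0.66, were estimated at -1.68 and -0.78. Of 300 unchanged random lists, 4.33% fell outside the central 95%. Both groups came from the same cells, so the simulation did not include the lower detection of the mutant cells. A changed gene stayed at 0 in the cells where it was at 0, and the unchanged lists were not made of genes that vary together. In all, 19 alternative settings fixed before the data were examined were run, and 4 were added afterwards. A further one, no filter on cells, was void because the filter removed no cell. The additions were 4 mutant-labelled cells left out, rescaling without 4 very abundant features, and each of the 2 subgroups of epithelial-like cells on its own.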

Results

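The series profiled 126 single cells of the mouse endolymphatic sac at E14.5, 33 labelled wild type and 93 labelled Sox9 Y440X/+. Sox9 and Sox10 encode related SOXE transcription factors, and the series title concerns how both control fluid homeostasis in the inner ear. The comparison asked how a heterozygous Sox9 Y440X allele alters the cells of the sac. A median of 5329 genes was listed above 0 FPKM in wild-type cells and of 4423 in mutant cells, so detection was lower in the mutant cells. The read depth is unknown.

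Sox9 itself was detected at a similar share in both genotypes, whereas Sox10 was detected in few mutant cells. In epithelial-like cells, the main class described below, Sox9 (ENSMUSG00000000567.5, mm10 chromosome 11, 112782224 to 112787760) was at 1 FPKM or more in 27 of 30 wild-type cells (90%, interval 73.5 to 97.9%) and in 68 of 77 mutant cells (88.3%, 78.97 to 94.5%). Its mean log2(FPKM + 1) was 3.37 ± 1.69 (SD over 30 cells) and 3.17 ± 1.49 (SD over 77 cells). The allele cannot be read from gene-level values, so these levels do not check the genotype labels. Sox10 (ENSMUSG00000033006.9, chromosome 15, 79154913 to 79164490) was detected in 24 wild-type cells (80%, 61.4 to 92.3%) and in 9 mutant cells (11.7%, 5.49 to 21.03%). Its mean level was 3.47 ± 2.07 in wild-type and 0.41 ± 1.15 in mutant cells, a relative difference of -2.51. Both factors were detected together in 21 of 30 wild-type cells (70%, 50.6 to 85.3%) and in 6 of 77 mutant cells (7.79%, 2.91 to 16.2%). Over all cells the co-detection was 69.7% of 33 and 7.53% of 93. Of the other SOX factors in the list, Sox4 was detected in 53.3% and 58.4% of epithelial-like cells, Sox5 in 30% and 20.8%, and Sox6 in 46.7% and 25.97%. Sox2, Sox3 and the third SOXE gene Sox8 were listed at 0 in every cell.

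**Figure D1:**
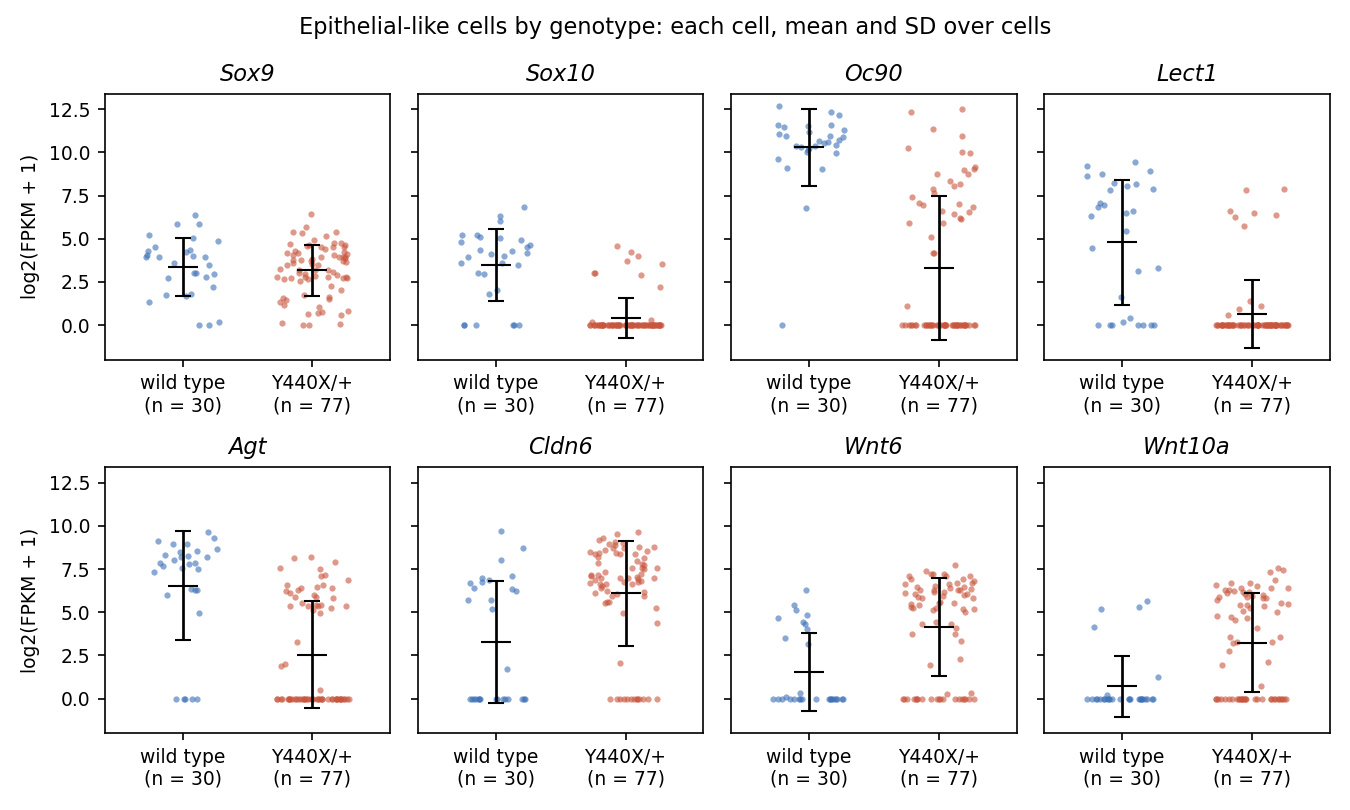
Levels of 8 genes in epithelial-like cells, as log2(FPKM + 1) on the vertical axis. Each point is a cell (30 wild type, 77 Sox9 Y440X/+), and the black bar is the mean ± SD over cells. Sox9 covered the same range in both genotypes, while most mutant cells lay at 0 for Sox10 and Lect1.

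By mean log2(FPKM + 1), the most strongly reduced of the ranked genes in the mutant epithelial-like cells was Oc90. It encodes otoconin 90, the main matrix protein of the otoconia. Oc90 (ENSMUSG00000015001.17, chromosome 15, 65876053 to 65912397) was detected in 29 of 30 wild-type cells (96.7%, 82.8 to 99.9%) and in 33 of 77 mutant cells (42.9%, 31.6 to 54.6%). Its mean log2 level was 10.28 ± 2.24 in wild-type and 3.32 ± 4.17 in mutant cells, a relative difference of -6.42. The mean FPKM was 1966.5 and 310.8, and on the log2 scale of these means the relative difference was -2.43, so its size depends on the scale. So does its first place. Mean FPKM fell proportionally more for Lect1, from 154.3 to 11.1, and for Sox10, from 21.7 to 1.35. In 8.10% of pairs of 1 mutant and 1 wild-type cell the mutant cell had the higher Oc90 value, ties counted equally to both sides.

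After Oc90, the lowest relative differences were those of Lect1 and Agt. Lect1, also called Cnmd, encodes the cartilage glycoprotein chondromodulin and was detected in 70% of wild-type and 11.7% of mutant cells, with a relative difference of -3.59. Agt, the angiotensinogen gene, was at -3.45 (detected in 83.3% and 42.9%). Fxyd3, which encodes a regulator of the sodium pump, was at -3.03 (96.7% and 70.1%). Next came the serine protease gene Prss56 at -2.92, the sphingosine kinase gene Sphk1 at -2.89, the glypican gene Gpc4 at -2.69 and the phospholipase gene Pla2g7 at -2.59. Fkbp11, which encodes a peptidyl-prolyl isomerase of the endoplasmic reticulum, was at -2.48 (60% and 11.7%). Pam16, which encodes a part of the mitochondrial import motor, was at -3.02, but its locus overlaps Glis2 and the strand setting is not known, so its value is uncertain. BC006965, a non-coding transcript at chromosome 11, 112663927 to 112781976, was at -2.78 (80% and 29.9%).

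At the high end stood 2 WNT ligands, a claudin and a feedback inhibitor of the EGF receptor. Errfi1, the feedback inhibitor, had a relative difference of 3.39 and was detected in 53.3% of wild-type and 83.1% of mutant epithelial-like cells. Cldn6, which encodes a tight junction claudin, was at 3.37 (50% and 83.1%). Wnt6 (chromosome 1, 74771892 to 74785322) was at 3.15 and detected in 33.3% and 71.4% of cells, and Wnt10a (chromosome 1, 74791516 to 74804179) was at 3.06 and detected in 16.7% and 59.7%. The neighbouring genes Wnt6 and Wnt10a do not overlap. Stat3, which encodes a transcription factor of cytokine signalling, was at 2.71 (53.3% and 87.01%). Its locus overlaps Stat5a and its value is uncertain for that reason. The actin-bundling plastin gene Pls3 was at 2.33, the adhesion gene Cadm2 at 2.31, the transmembrane gene Tmeff2 at 2.45 and the DNA glycosylase gene Tdg at 2.23. Avpi1, named for its induction by vasopressin, was at 2.28. Cbarp was at 2.32 and overlaps Stk11 and Atp5d, so its value is uncertain. Tsix, antisense to Xist and not separable from it without strand, was at 3.799 and is given with the sex-linked genes.

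Genes of ion and water transport were among those chosen beforehand. The sodium pump subunit gene Atp1b1 was detected in 53.3% of wild-type and 41.6% of mutant epithelial-like cells. Slc12a2, a sodium, potassium and chloride cotransporter gene, was detected in 13.3% and 10.4%. The water channel genes Aqp3 and Aqp4 were at 1 FPKM in 0 and 1 of 30 wild-type cells and in 0 and 1 of 77 mutant cells, where 0 of 30 allows a share of up to 10% and 0 of 77 a share of up to 3.90%. The pan-epithelial gene Epcam was detected in 96.7% and 93.5%. The otic transcription factor genes Dlx5 and Pax2 were detected in 90% and 20% of wild-type and in 87.01% and 23.4% of mutant cells. Wnt2b was detected in 33.3% and 28.6%, Spp1 in 70% and 74.03%, and Bmp4 in 0 and 1 cells. Col2a1, a cartilage collagen gene, was detected in 43.3% and 14.3%.

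Of 23 fixed gene lists with at least 3 usable members, 4 had a median outside the central 95% of matched random lists, where 1.15 would be expected of random lists. Known SOX9 targets of the cartilage matrix were lower, with a median 0.58 log2 units below the random median (percentile 0.34, 9 members used). Lect1 was lowest in this list at -3.59 and Hapln1 highest at 1.03, and Col9a3 stood at -1.19. Of the 9 members, 2 lay above the random median. The list of WNT targets lay higher, by 0.61 (percentile 99.9, 8 members). Lef1 led them at 1.95, followed by Notum at 1.67 and Ccnd1 at 1.15, and Nkd1 was lowest at 0.21. Of these 8 members, 7 lay above the random median, but Axin2 was detected in 16.7% and 15.6% of cells. Epithelial adhesion and keratin genes were higher by 0.41 (percentile 99.6, 19 members), from Cdh2, the N-cadherin gene, at 2.05 to Krt19 at -1.63. The sex-linked list was the remaining one (percentile 0.0). It pools Xist at 3.57 with Y-linked genes such as Eif2s3y at -3.15. Its place restates the difference in sex-linked transcripts described below and is not a separate result. The WNT and cartilage matrix medians each fell outside the central 95% in 12 of 15 alternatives and the adhesion median in 10 of 15. Among cells with 3000 to 5000 listed genes, the WNT list was at percentile 87.8. Without the cells above 6000 listed genes, the cartilage matrix list was at percentile 6.54 and the adhesion list at 83.9.

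The other 19 lists lay between percentile 4.47, for the unfolded protein response, and 97.0, for p53 targets. Of the 8 p53 targets used, from Mdm2 at 0.12 to Cdkn1a at 1.34, 7 lay above the random median of 0.23. In the unfolded protein response list, Calr was lowest at -1.43 and Asns highest at 0.90. Tight junction genes as a list stood at percentile 64.6, with Cldn6 at 3.37 and Cldn10 at -1.73. Ubiquitous V-ATPase subunits stood at 22.9, sodium and potassium transport at 48.3, and otic and sac patterning factors at 15.9. Glycolysis and hypoxia genes were at percentile 92.9, NOTCH pathway genes at 91.9, BMP and TGF-beta targets at 87.1, FGF targets at 76.9, cytosolic ribosomal protein genes at 48.8, basement membrane and matrix genes at 13.7 and nuclear genes of oxidative phosphorylation at 5.53. The list of inner ear secreted proteins had 2 usable members, Oc90 and Spp1, and was given no percentile. Marker lists of other cell types had at most 3 usable members in the epithelial-like cells and decide little. Mesenchymal genes were at percentile 55.5 and glial and neural crest genes at 31.8, where Cdh6 stood at 1.78 and Sox10 at -2.51. The immediate early and heat shock genes that respond to tissue dissociation were at percentile 42.99.

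**Figure D2:**
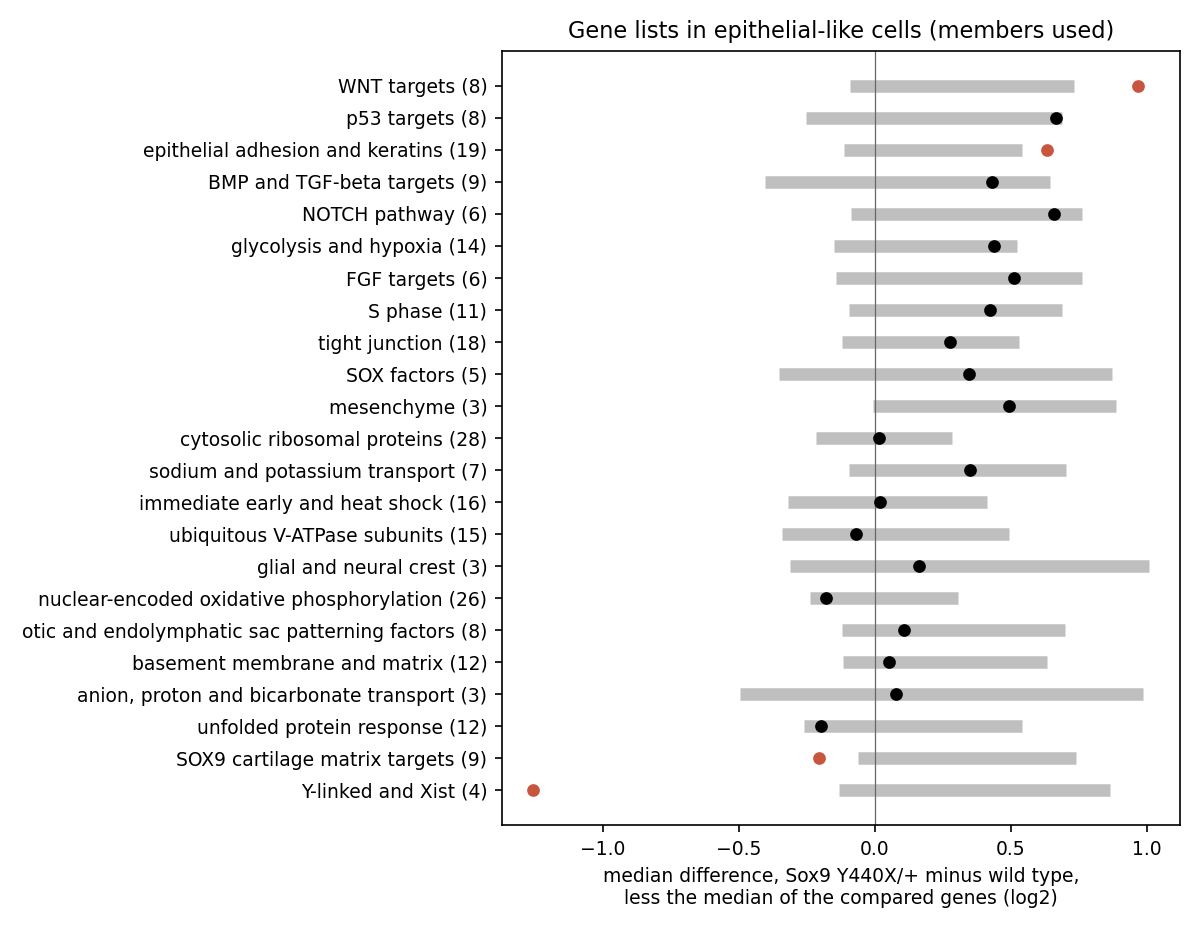
Median relative difference of each gene list in epithelial-like cells, Sox9 Y440X/+ minus wild type, on the log2 scale. Points are list medians, red where outside the grey bar, and the bar spans the central 95% of 10000 matched random lists. WNT targets lie 0.61 above and SOX9 cartilage matrix targets 0.58 below their random medians.

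Clustering separated 3 named classes. Epithelial-like cells made up 30 of 33 wild-type cells (90.9%, 75.7 to 98.1%) and 77 of 93 mutant cells (82.8%, 73.6 to 89.8%). Within this class the genotypes fell into partly different clusters. Clusters 0 and 1 held 34 and 25 mutant cells and 0 wild-type cells, clusters 2 and 3 held 16 and 12 wild-type cells with 8 mutant cells each, and a small cycling cluster held 2 cells of each genotype. Mitochondria-rich-like cells, the acid and anion transporting cells of the sac that express Foxi1, made up 3 of 33 wild-type cells (9.09%, 1.92 to 24.3%) and 9 of 93 mutant cells (9.68%, 4.52 to 17.6%). Of these 9 mutant cells, 2 have a doubtful label, being among the 4 mutant-labelled cells with Y-linked transcripts described below. Without those 4 cells, 7 of the 89 other mutant cells were in this class, so the shares of the genotypes stayed alike. Shares with the doubtful cells counted as wild type are not given. Mesenchymal-like cells numbered 7 in the mutant (7.53%, 3.08 to 14.9%) and 0 of 33 in the wild type, which allows a share of up to 9.09%. With 1000 variable genes, clustering put 3 wild-type cells (9.09%) and 9 mutant cells (9.68%) in this class. These shares can be set by the dissection, and their intervals overlap.

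**Figure D3:**
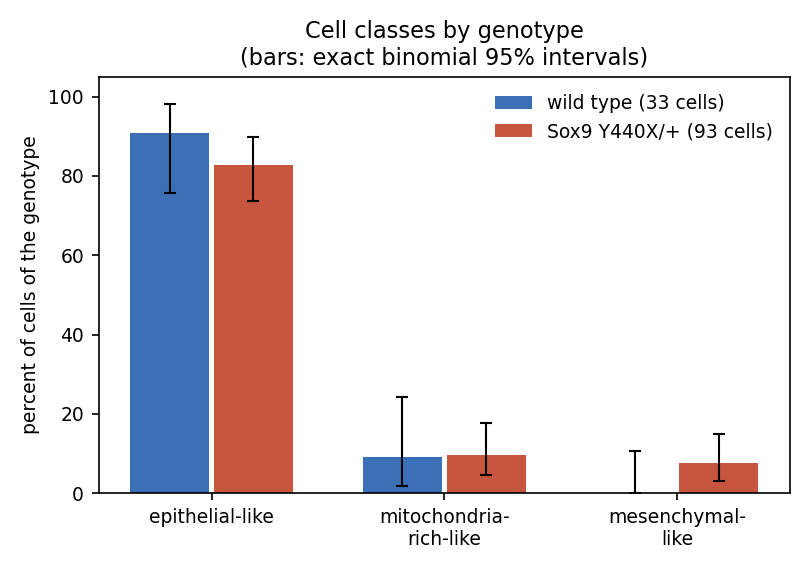
Percent of the cells of each genotype in each class (33 wild-type and 93 Sox9 Y440X/+ cells), with exact binomial 95% intervals as error bars. The mitochondria-rich-like share was 9.09% and 9.68%, the latter with 2 mutant-labelled cells of doubtful label.

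The mitochondria-rich programme was found in both genotypes. At least 3 of its 10 markers were detected in 3 of 33 wild-type (9.09%, 1.92 to 24.3%) and 9 of 86 mutant cells (10.5%, 4.90 to 18.9%) of the epithelial-like and mitochondria-rich-like classes together. Foxi1, the transcription factor gene that directs this cell type, was detected in 15.2% and 12.8% of these cells. Slc26a4, which encodes the anion exchanger pendrin, was detected in 6.06% and 8.14%, and the V-ATPase subunit gene Atp6v1b1 in 6.06% and 9.30%. Car2, a carbonic anhydrase gene, was detected more widely, in 78.8% (61.1 to 91.02%) and 58.1% (47.01 to 68.7%). In the mitochondria-rich-like cells alone, mean log2 Foxi1 was 8.58 ± 0.51 in 3 wild-type and 7.97 ± 0.97 in 9 mutant cells, and Slc26a4 was 7.21 ± 6.25 and 6.29 ± 3.74. With 3 wild-type cells, and with 2 of the 9 mutant cells of doubtful label, differences within this class are not resolved.

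Cycling cells, with at least 5 of 20 G2 and M phase genes at 5 FPKM or more, made up 3 of 33 wild-type cells (9.09%, 1.92 to 24.3%) and 4 of 93 mutant cells (4.30%, 1.18 to 10.6%). Among epithelial-like cells the shares were 10% (2.11 to 26.5%) and 2.60% (0.32 to 9.07%). The intervals overlap, but they cover counting error only and no test was made, so they do not decide whether the shares differ. Without cells above 6000 listed genes the shares of all cells were 3.70% and 3.37%. S phase genes as a list stood at percentile 70.3.

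The genotypes also differed in sex-linked transcripts, a difference that goes with every comparison above. A Y-linked gene (Ddx3y, Eif2s3y, Kdm5d or Uty) was at 1 FPKM or more in 32 of 33 wild-type cells (97.0%, 84.2 to 99.9%) and in 4 of 93 mutant cells (4.30%, 1.18 to 10.6%). Xist, the non-coding RNA of the inactive X chromosome, was detected in 0 of 33 wild-type cells, which allows a share of up to 9.09%, and in 81 of 93 mutant cells (87.1%, 78.5 to 93.2%). Genotype therefore nearly coincides with sex-linked expression, and with the title prefix except for 1 cell. Of the named genes, Gpc4, Pls3 and Tsix lie on chromosome X. The 4 mutant-labelled cells with a Y-linked transcript had Xist at 0. Leaving out these 4 cells put the share of mutant epithelial-like cells with Sox10 at 9.33%, Sox10 at a relative difference of -2.57 and Oc90 at -6.59.

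**Figure D4:**
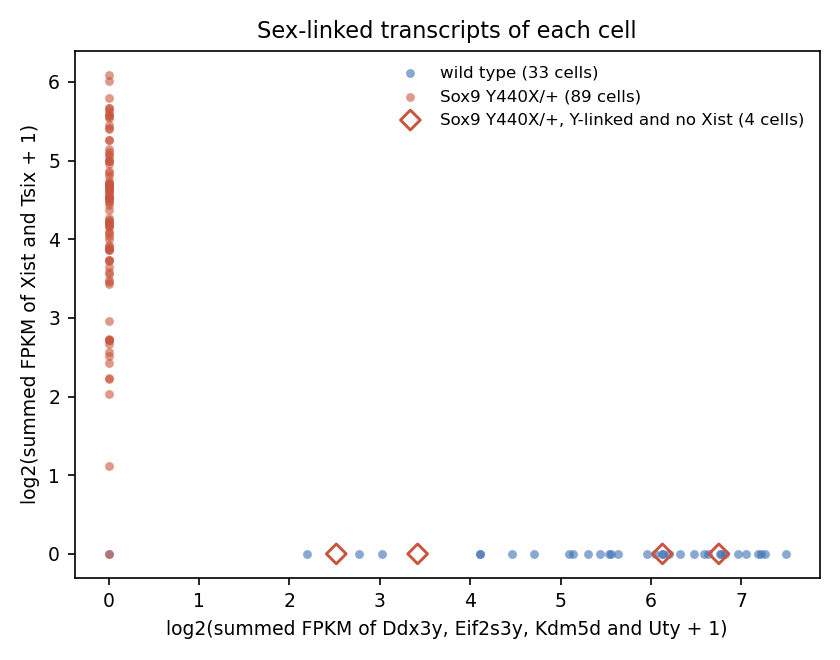
Summed FPKM of Xist and Tsix against that of 4 Y-linked genes, both as log2(sum + 1), for each of 126 cells. Diamonds mark the 4 cells labelled Sox9 Y440X/+ that lie with the wild-type cells along the horizontal axis.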

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

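The 24 named genes kept their sign in all 360 pairs of a gene and an alternative, but their selection required this in 2 of the 15 alternatives, matched cells and rescaling to 1000000. In 6 pairs the value moved by more than 1 SD over cells, for Tsix, Oc90 and Sox10. Relative differences of Sox10 ranged from -4.36, with a pseudocount of 0.1, to -0.95, with a pseudocount of 10. That of Sox9 ranged from -0.20 to 0.89 around 0.35 and has no stable sign. No called value reversed. Of the values that answer a comparison, 176 stayed within their spread and 37 moved. Of the others, 609 stayed and 45 moved. The cause was not tested except where given. A filter of 2000 listed genes removed no cell, so the planned setting without it was not run. The settings that left out the 4 mutant-labelled cells, rescaled without abundant features or took each subgroup alone were chosen after seeing the data. No paired analysis was possible because the labels number no replicates in common and no test was made.

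The list values that follow are medians less the matched random median. With cells above 6000 listed genes left out, SOX9 cartilage matrix targets were at -0.35 and adhesion genes at 0.17. Among cells with 3000 to 5000 listed genes, where 12 wild-type and 52 mutant epithelial-like cells remained, the cartilage list was at -1.02 and the WNT list at 0.34. In the same setting the 12 wild-type cells were all epithelial-like (100%). Their shares of mitochondria-rich-like cells, of cells with 3 mitochondria-rich markers and of cycling cells were 0%, because the window left such cells out. The 3 wild-type mitochondria-rich-like cells listed 6222, 5520 and 5899 genes. Pseudocounts of 0.1 and 10 gave the cartilage list -0.83 and -0.24, the WNT list 1.12 and 0.20, and the sex-linked list -3.13 and -0.61, and a pseudocount of 10 gave the adhesion list 0.17. Rescaling to 1000000 gave the WNT list 0.82 and the sex-linked list -2.06, and 0.84 and -2.23 without 4 abundant features. Median-ratio scaling gave the adhesion list 0.24 and the sex-linked list -1.38. The log2 of the mean FPKM gave the cartilage list -0.80 and the sex-linked list -3.31. Without a filter on low values, the cartilage list was at -0.16 and the WNT list at 0.13, since undetected members enter at 0. In subgroup 0 alone the cartilage, adhesion and WNT lists were at -0.28, 0.094 and 0.35, and in subgroup 1 the cartilage and WNT lists were at -1.56 and 0.97. Detection above 0 FPKM put Sox9 in 97.4% of mutant cells. Detection at 5 FPKM put it in 73.3% of wild-type and 74.03% of mutant cells and co-detection with Sox10 in 2.60% of mutant cells, as a stricter level must. At resolution 0.5 the 7 mesenchymal-like cells and 1 mitochondria-rich-like mutant cell joined epithelial-like clusters, so that the mutant shares were 91.4% epithelial-like and 0% mesenchymal-like. The read depth is unknown, and detection of scarce genes is limited by capture in single cells.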

Other observations

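The tests of the P9 prefix, of detection, of subgroups and of doublets, and the gene lists of the next paragraph, were chosen after the results were seen. The comparison with mean profiles was written down before its result was seen, but the use of P9-H12 to judge it was added after.

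In 2 gene lists made after the results were seen, members had lower medians than matched random lists over all epithelial-like cells but not clearly in subgroup 0, and no independent cells were at hand to test this. Of 36 genes of endoplasmic reticulum protein folding and translocation, 35 were usable, and their median relative difference was -0.52, against 0.08 for matched random lists (percentile 0.0). Ssr4, a part of the translocon, was lowest at -1.44, and Rcn2 was highest at 1.53. Of 32 lysosomal enzyme and membrane protein genes, 31 were usable, with a median of -0.36 against 0.12 (percentile 0.04), and Scarb2 was highest at 0.77. Without any gene among the 200 lowest and 200 highest compared genes, the medians were -0.46 (percentile 0.01) and -0.32 (percentile 0.11). Among cells with 3000 to 5000 listed genes they were -0.49 and -0.80. Their medians were -0.40 and -1.03 in subgroup 1 and -0.08 and -0.11 in subgroup 0, where they stood at percentiles 18.8 and 10. The fixed list of the unfolded protein response was at percentile 4.47, and outside the central 95% in 3 of 15 alternatives. Whether the subgroups differ was not tested.

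At resolution 0.5 the epithelial-like cells formed 2 subgroups that held both genotypes in like proportion. Subgroup 0, led by Aldh1a1, Klk10, Rcan2 and Spp1, held 53.3% of wild-type and 55.8% of mutant cells. Subgroup 1, led by Aldh1a3, Id3, Id1 and Igfbp2, held 46.7% and 44.2%. Oc90 was detected in 26.5% of mutant cells of subgroup 1 (12.9 to 44.4%) and in 55.8% of those of subgroup 0 (39.9 to 70.9%). Some relative differences were uneven. Fxyd3 was at -1.75 in subgroup 0 and -4.80 in subgroup 1, Prss56 at -1.35 and -4.80, and Lect1 at -5.00 and -1.98. Sox10 was at -2.46 and -2.60. These differences between subgroups were not tested. All 9 mutant epithelial-like cells with Sox10 also had Oc90, where the product of the shares gives 3.86 cells. Without the 4 doubtful cells these numbers were 7 and 2.89. Of the mitochondria-rich-like cells, 3 of 3 wild-type and 2 of 9 mutant cells had Oc90, and these 2 were among the 4 doubtful cells. It was not detected in the other 7, where 0 of 7 allows a share of up to 42.9%.

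The non-coding transcript BC006965, annotated on the opposite strand, lies 247 bases upstream of Sox9 on chromosome 11, head to head with it. It was at a relative difference of -2.78, while Sox9 was at 0.35. Wnt6 and Wnt10a, 6193 bases apart, were detected together in 48.1% of mutant epithelial-like cells (36.5 to 59.7%) and 6.67% of wild-type ones (0.82 to 22.1%). The products of their shares give 42.7% and 5.56%, so joint detection added little to the single shares.

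Sox10 and Oc90 were detected in fewer mutant than wild-type epithelial-like cells. Lower detection per cell as the whole cause is argued against by the 14 mutant cells with at least the wild-type median of listed genes, of which 14.3% had Sox10 (1.78 to 42.8%) and 50% had Oc90 (23.04 to 76.96%), below the wild-type intervals of 61.4 to 92.3% and 82.8 to 99.9%. A different mix of the 2 subgroups could not have produced this, since they held both genotypes in like proportion. Within them, 11.6% and 11.8% of mutant cells had Sox10, against 81.2% and 78.6% of wild-type cells. At resolution 1, clusters 0 and 1 held 0 wild-type cells, so a different mix of these finer clusters was not tested and stays open. An effect of the plate, if the prefix marks one, of the animal or of the sex cannot be told apart from the genotype. Only 1 wild-type epithelial-like cell, P9-H12, carries the P9 prefix. It had Sox10 at 22.03 and Oc90 at 2168.3 FPKM, but the profile comparison below placed it with the mutant, and 1 cell cannot decide. An effect of the Sox9 genotype stays open as well and was not tested apart from plate, animal and sex.

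The 4 mutant-labelled cells with Y-linked transcripts and no Xist are titled P9-D12, P9-E12, P9-F12 and P9-G12. They share the title ending 12 with P9-H12, the wild-type cell that carries P9. They share it also with P9-A12, P9-B12 and P9-C12, mutant-labelled cells with Xist or Tsix and no Y-linked transcript. By letter, the titles P9-D12 to P9-H12 follow each other without a gap, and no other cell with the P9 prefix had a Y-linked transcript. The labels do not say what the order of titles means. The run goes with a shared genotype of the 4 cells and P9-H12 as well as with a shared sex. Over 3248 autosomal genes without Sox10 and Oc90, 2 of the 2 that were epithelial-like correlated better with the wild-type than with the mutant mean profile. This rule placed 90% of wild-type and 93.3% of the other mutant epithelial-like cells with their label. However, it placed P9-H12 with the mutant and P9-B12 and P9-C12 with the wild type. Epithelial-like cells listed a median of 5120.5 genes in the wild type and 4340 in the mutant. Whether this moved the placements was not tested. Oc90 was detected in all 4 and Sox10 in 3, which goes with wild type, while Wnt6 was detected in all 4, which goes with the mutant. Of the 4, 2 were epithelial-like, a class in which 29 of 30 wild-type and 31 of 75 other mutant cells had Oc90 and 10 and 53 had Wnt6. The other 2 were mitochondria-rich-like, where 3 of 3 wild-type and 0 of 7 other mutant cells had Oc90 and 1 and 6 had Wnt6. P9-F12 and P9-G12 listed 9358 and 8246 genes, more than any other cell of either label. The highest of the others listed 7074 in the mutant and 6493 in the wild type, so these counts do not separate the labels. Whether the 4 are wild-type cells with the wrong label thus cannot be told from these values. Doublets of a mutant and a wild-type cell are argued against by Xist or Tsix, detected in 0 of the 4 and in 97.8% of the other mutant cells. A male mutant embryo stays open, since 0 other mutant epithelial-like cells had a Y-linked transcript, so that sex and label cannot be told apart.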
